A study of Homo sapiens with 8 samples.

How the data were processed

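Total RNA was taken, per the labels, from the nasal squamous cell carcinoma line RPMI2650 and the CDDP-resistant line RPMI2650CR, with or without CDDP at 10 µg/ml for 0.25 of a doubling time, in duplicate. It was labelled with Cy3 and hybridised to 8 one-colour Agilent human miRNA arrays on 2 slides, each slide holding 1 array of each of the 4 groups. The deposited files hold, per array, spot intensities from Agilent Feature Extraction (9.5.1 per the labels, 9.5.3.1 per the file headers), made with an additive spatial background subtraction, no multiplicative detrending and no surrogate values, on a linear scale and not scaled between arrays. The deposited gene tables hold the total gene signal per miRNA in the same intensity units with a detection call. The deposited value table equals that signal in 961 of 961 entries and was not scaled between arrays. All 8 arrays differed from each other.

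Each array carries 15024 spots of 2689 probes for 939 miRNAs, with 1 to 4 probes per miRNA and 4 to 16 spots per probe, and 715 control spots, which were left out. Spots marked as outliers, 6.56% to 8.83% per array, were left out as well. The processed signal was averaged over the spots of a probe and summed over the probes of a miRNA. Signals were then scaled by the 75th percentile over the 270 miRNAs detected on all 8 arrays, floored at 5.88, the median over arrays of the lowest scaled signal of a detected miRNA, and turned to log2. A miRNA was tested when it was detected on both arrays of at least 1 group, which held for 340. Names of miRNAs are those of the array files, and no genome position was used for the values. For array data, the number of arrays limits the precision.

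All contrasts came from 1 limma fit (lmFit and eBayes, two-sided) to the 4 group means over the 8 arrays, with 4 residual and 2.17 prior degrees of freedom and Benjamini-Hochberg adjustment over the 340 miRNAs within a comparison, called at an adjusted p under 0.05. The 7 comparisons were the lines untreated, under CDDP and averaged over treatment, CDDP in parental cells, in resistant cells and averaged over lines, and the difference of the CDDP effects. A change is written as log2 of resistant over parental or of CDDP over control. Where a miRNA was undetected on both arrays of a group, the change is given as a lower bound, computed against the highest of the floor, the array's lowest detected signal and the measured signal. That lowest signal is of any miRNA, and undetected ones can measure above it. miR-335*, for example, was undetected in resistant control cells at a mean log2 signal of 4.75. A bound is thus not set by the detection limit of the miRNA itself, which matters most for dim miRNAs. R 4.3.3 and limma 3.58.1 were used.

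Lists of miRNAs were fixed before the data were examined, as were the tests of the comparisons and of the lists, the rule for naming miRNAs and all alternatives but 1. Of the tests of explanations in the closing section, some were chosen later, as is said there. There were 21 lists: p53-induced miRNAs, the miR-17-92 and paralogous clusters, the miR-200, let-7, miR-15/16, miR-29, miR-30 and miR-181 families, squamous epithelium miRNAs, the miR-23/27/24 clusters, the cluster of miR-221 and miR-222 and other growth-promoting miRNAs, miRNAs that repress DNA repair or damage signalling genes, the 14q32, 19q13 and Xq26-27 clusters, a hypoxia-induced miRNA, fibroblast, blood cell, endothelial and neuron, muscle and liver miRNAs as markers of other cell types, and viral miRNAs. The 13 lists with at least 3 tested members were tested against the other miRNAs with camera, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists. With fry, adjusted alike, it was tested whether the members of a list moved on balance one way, without regard to the other miRNAs. miR-18a and miR-24 stand in the DNA repair list and in a cluster list each. A list of fragments of tRNA and rRNA was added after the data were seen and was not tested as a set.

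Named were, per comparison, the 12 largest rises and the 12 largest falls among called miRNAs whose arrays did not overlap between the groups, or, where fewer than 5 were called, the 5 of smallest p in each direction, along with miR-34a, up to 4 members of each list that passed and up to 2 of highest signal of each other list. The result of every list is given for the untreated lines, and elsewhere mostly those of lists that passed.

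The alternatives were the deposited total gene signal scaled alike, the deposited value table unscaled, the brightest probe of each miRNA, a normexp background with an offset of 50, scaling by the 75th percentile over all miRNAs, quantile normalization, no scaling, only miRNAs detected on all 8 arrays, no filter, a floor 4 times lower, the replicate number as a fixed block, the slide as a random block, only the arrays of the groups compared, eBayes with trend and robust, and each array left out in turn. A filter at a mean scaled signal of 50 was added after the data were seen. Residuals of arrays with the same replicate number correlated by 0.18 to 0.66 in 6 of 6 pairs, so the number, which is also the slide, pairs the arrays. On each slide the lines occupy different array rows and the treatments different array columns, so line goes with row and CDDP with column.

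The pipeline was tested on simulated data with planted changes. Between the untreated lines it recovered 45.5% of changes of 0.5, 85.5% of changes of 1 and 99.3% of changes of 2 on the log2 scale, and for CDDP in parental cells 41.3%, 88.5% and 98.8%. It called at most 0.821% of miRNAs without a change. A list shifted by -0.5 was recovered by camera with the preset correlation in 100% of 20 runs. The simulated noise was independent between miRNAs and arrays, with no slide effect and no floor, and smaller list shifts were not planted. The runs therefore do not show how list calls behave where miRNAs are correlated.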

Results

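MicroRNAs (miRNAs) were measured in RPMI2650, a human nasal squamous cell carcinoma line, and in RPMI2650CR, its CDDP-resistant counterpart. CDDP is cisplatin, a platinum drug that crosslinks DNA. Each line was left untreated or exposed to CDDP at 10 µg/ml for 0.25 of a doubling time. There were 4 groups with 2 arrays each, 8 arrays in all, called here parental control, parental CDDP, resistant control and resistant CDDP. Nothing in the labels says whether the replicates were separate cultures. Each array reported 939 miRNAs, of which 851 were human and 88 viral. Between 282 and 347 miRNAs were detected per array, with 327 to 347 on the parental arrays and 282 to 318 on the resistant arrays. No spot was saturated, and 340 miRNAs were tested. Across miRNAs, which are not independent replicates, Pearson's r was 0.988 to 0.994 between arrays of 1 group, 0.989 to 0.997 between treatments of 1 line and 0.884 to 0.894 between the lines. With 2 arrays per group, their number limits the precision. The prefix hsa- is left out of the names of human miRNAs below. Arm names are those of the array files, which mark the minor product of a precursor with an asterisk.

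miR-34a, a miRNA that p53 induces and that represses cell cycle genes, was lower in the resistant line, as were 3 of the 4 other products of its family that were tested. The mean scaled signal of miR-34a, the miRNA of the series title, was 4055 ± 445 (SD, n = 2) in untreated parental cells and 415 ± 67.1 (SD, n = 2) in untreated resistant cells. This was a log2 change of -3.29 ± 0.17 (SE, limma adjusted p = 1.8e-05), or 9.80-fold lower, with both resistant arrays below both parental arrays. miR-34b* was lower by a log2 change of -3.70. Neither the minor arm miR-34a* nor miR-34c-5p was detected on a resistant control array. Against the lowest signals detected there for any miRNA, they were at least 6.58-fold and 2.86-fold lower. With a normexp background, however, both calls were lost and miR-34c-5p had a value of 0.09 (adjusted p = 0.64). miR-34b had a change of -0.23 (adjusted p = 0.66). The family was not tested as a list of its own. Under CDDP the change of miR-34a between the lines was -3.33 ± 0.17 (adjusted p = 1.9e-05), and averaged over treatment it was -3.31 ± 0.12 (adjusted p = 2.3e-06). On each slide taken alone, miR-34a was lower in the resistant line by a log2 change of -3.24 and -3.35 without CDDP, and of -3.27 and -3.40 with it. CDDP itself gave miR-34a values of 0.19 ± 0.17 (adjusted p = 0.99) in parental and 0.15 ± 0.17 (adjusted p = 0.98) in resistant cells, and the difference of these effects was -0.04 ± 0.25 (adjusted p = 1.00). On the slides taken alone CDDP gave 0.17 and 0.21 in parental and 0.14 and 0.16 in resistant cells. Averaged over lines, CDDP gave 0.17 ± 0.12 (adjusted p = 0.77). The 95% intervals of the CDDP values reached from -0.24 to 0.61 in parental and from -0.28 to 0.57 in resistant cells.

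**Figure D1:**
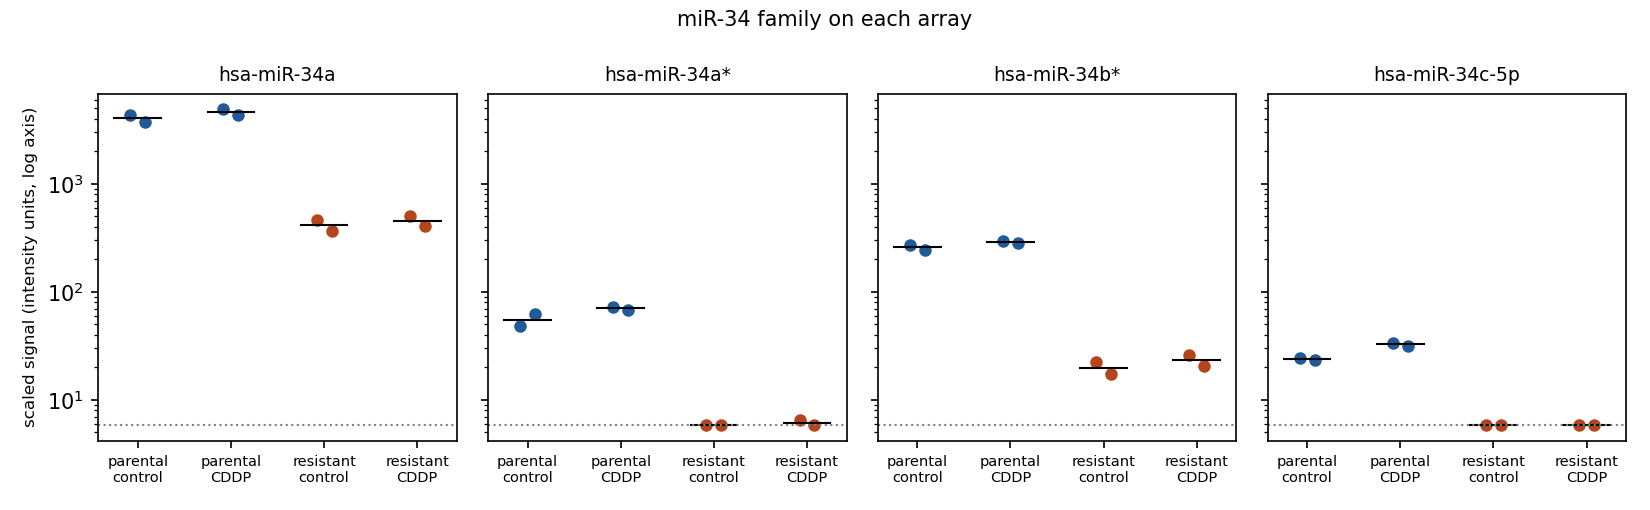
Scaled signal (intensity units, log axis) of 4 products of the miR-34 family, 1 panel each, in the 4 groups. Each point is 1 array (blue parental, orange resistant), each bar the geometric mean of 2 arrays, and the dotted line the floor of 5.88, at which lower signals are drawn. miR-34a lies near 4055 in untreated parental cells and near 415 in untreated resistant cells.

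The first comparison asked how the resistant line differed from the parental line without drug. The loss of miR-124, a neuronal miRNA, was the largest difference: its mean signal was 12217 ± 1196 (SD, n = 2) in parental cells and it was undetected in resistant cells, at least 1465-fold lower. Its minor arm miR-124* was at least 12.7-fold lower. miR-9*, from another miRNA of neurons, was lower by a log2 change of -3.09. Also lower were the pair miR-181c* (-2.39) and miR-181c (-2.16). Undetected in resistant cells and lower were miR-363 (at least 4.70-fold), miR-654-5p (at least 4.52-fold), miR-628-5p (at least 4.15-fold) and miR-95 (at least 3.45-fold). In the other direction, the neighbouring miRNAs of the miR-216a, miR-216b and miR-217 cluster were detected in resistant cells alone, at least 20.7-fold, 12.96-fold and 7.55-fold higher. miR-483-5p and miR-483-3p, encoded within the imprinted gene IGF2, were higher by 3.45 and 2.96. The signal of miR-483-5p was 44.6 ± 0.600 (SD, n = 2) in parental and 486 ± 19.9 (SD, n = 2) in resistant cells. miR-10a, encoded among the HOXB genes, was higher by 3.22, miR-210, which hypoxia induces, by 2.27, and miR-335, encoded within MEST, by 2.22. Products of the miR-23b cluster were higher as well, with 3.03 for miR-24-1*, 2.45 for miR-23b, 2.36 for miR-27b and at least 6.06-fold for miR-23b*.

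Of the 340 miRNAs tested, limma called 166 at an adjusted p under 0.05, 87 higher and 79 lower in resistant cells. Fitted changes were at least 2-fold in 29 and 54, with signals under the floor taken at the floor. These counts include miR-369-3p, miR-656 and miR-675, whose lower bounds were only 1.67-fold, 1.88-fold and 1.73-fold. The 79 include miR-300, undetected on every array of both groups, which is not read as a change. The arrays of the groups did not overlap for 166 of the 166 called and for 70.3% of all 340, where chance gives 33.3%. With a normexp background, 112 were called, the share called higher was 71.4% against 52.4%, and the calls of miR-124*, miR-34a*, miR-34c-5p, miR-181c, miR-181c*, miR-363, miR-628-5p, miR-654-5p and miR-95 were lost, 6 of them with the opposite sign. With the brightest probe of each miRNA, 36.6% of the calls were higher and the median change of all miRNAs was -0.18 against 0.06.

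The miRNAs of the imprinted 14q32 cluster, expressed from the maternal chromosome in the DLK1-DIO3 region, were lower in the resistant line as a group. Of the 39 tested members of the fixed list, 37 were lower and 0 higher, and 37 were lower when adjusted over the list alone. The list does not hold the whole locus. By gene name and steps within 50 kb, 36 genes of tested miRNAs lay there, 29 of them listed. Unlisted miRNAs of the locus stayed among the other miRNAs in the list tests. The 37 called over all tested include miR-493, for which no fall is shown. It was undetected in resistant control cells, and its parental mean of 3.03 on the log2 scale lay below the limit of 3.06 there. The median change was -1.19. miR-381 (-1.92), miR-370 (-1.90) and miR-127-3p (-1.87) changed most among those detected in both lines, and miR-485-5p was at least 3.14-fold lower. miR-494, with a change of 0.01, and miR-487a, with -0.45, did not pass. The list was lower against the other miRNAs with the preset correlation of camera (adjusted p = 3.1e-18), and not with an estimated one (adjusted p = 0.32 with an estimated correlation). Taken alone, its members moved on balance downward (fry adjusted p = 9.8e-05). On the slides taken alone the median was -1.11 and -1.28. With a normexp background it was smaller, -0.32, miR-370 lost its call and miR-485-5p had a value of 0.24, while the list still passed.

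**Figure D2:**
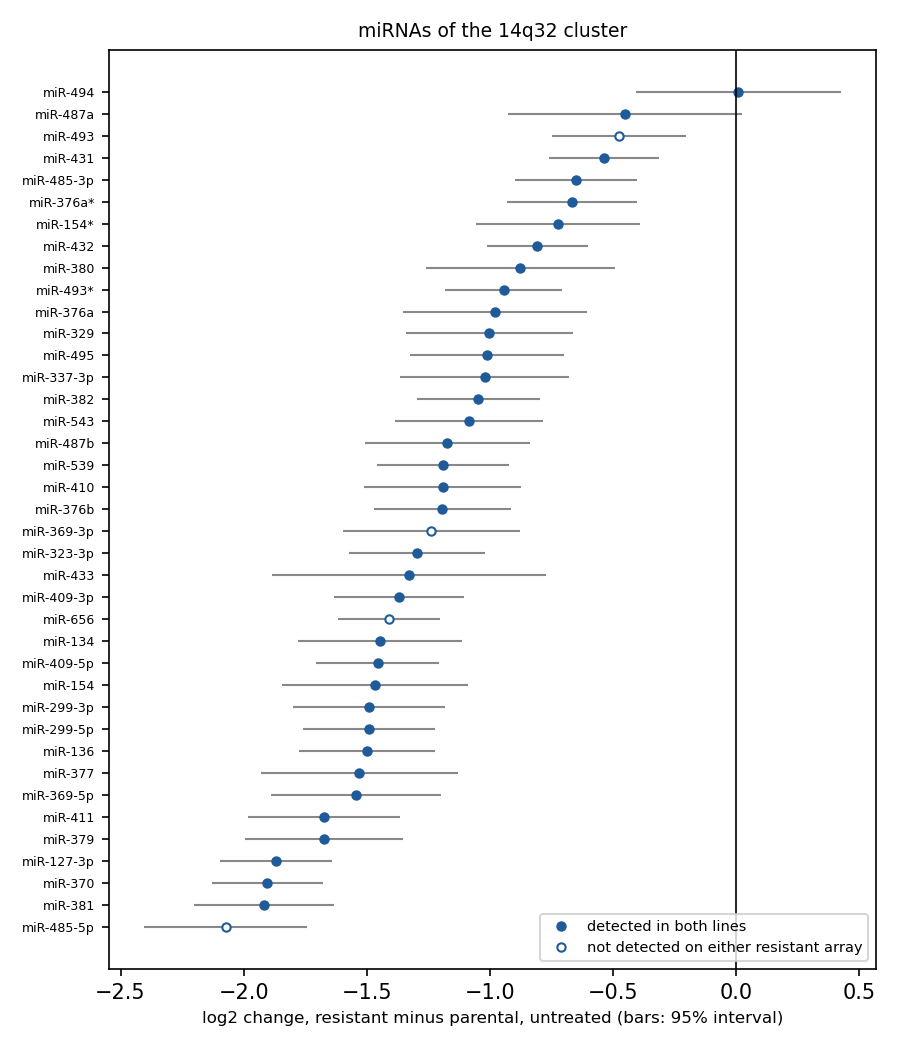
Log2 change (resistant minus parental, untreated) of each of the 39 tested miRNAs listed for the 14q32 cluster, 1 per line, with its 95% interval from the limma fit. Open points mark miRNAs undetected on both resistant arrays, whose fitted values rest on the floor. The points lie below 0 for 38 of 39, around a median of -1.19.

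Among markers of other cell types, 3 tissue-restricted miRNAs of the list for neuron, muscle and liver were tested, miR-124, miR-9 and miR-9*, all of them neuronal. All 3 were lower, also when adjusted over the list alone, with -1.76 for miR-9. The list passed with the preset correlation (adjusted p = 3.3e-03) and not with an estimated one (adjusted p = 0.32 with an estimated correlation). miR-126, a miRNA of endothelial cells, was higher by 0.66, its call the same when adjusted over the list alone. The blood cell miRNAs miR-150 and miR-486-5p had changes of 0.01 and -0.19, 0 of 2 called either way. No fibroblast marker, no miRNA of squamous epithelium and no member of the 19q13 placental cluster was among the miRNAs tested. The epithelial miR-200 family had 2 tested members, miR-141 with 0.38 and miR-200c with 0.14, and 0 calls either way. Features of the array that match fragments of tRNA and rRNA, listed after the data were seen, were higher in 4 of 8 and in 6 of 8 when adjusted over the list alone, with a median change of 0.84. They include miR-1274a (1.66), miR-1274b (1.02) and miR-720 (1.02), the latter 2 not called with quantile normalization (adjusted p = 0.41 and 1.00). The slides differed in size, with 1.95 on slide 1 and 1.37 on slide 2 for miR-1274a. For miR-1274b these values were 1.34 and 0.71, and for miR-720 1.25 and 0.80. Fewer miRNAs were detected on the resistant arrays than on the parental ones, beside the lower signals of the 14q32 cluster and the neuronal miRNAs.

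The clusters of miR-23, miR-27 and miR-24 were higher in 3 of 5 tested members, and in 4 of 5 when adjusted over the list alone, with miR-23b at 2.45, miR-27b at 2.36 and miR-24 at 2.10. miR-23a had 0.33 (adjusted p = 0.052, and 0.034 with the replicate number as a block, against 0.027 to 0.40 over the alternatives). The list passed with the preset correlation (adjusted p = 0.020) and not with an estimated one (adjusted p = 0.59 with an estimated correlation). Without parental control replicate 2 its adjusted p was 0.051, against 0.0078 to 0.051 over the alternatives. miRNAs that repress DNA repair or damage signalling genes were higher in 4 of 7, and in 5 of 7 when adjusted over the list alone. They were miR-24, which targets H2AX and stands in the clusters above too, miR-421 (1.24) and miR-18a (0.70), which target ATM, and miR-101 (0.62). With the brightest probe of each miRNA the call of miR-18a was lost (adjusted p = 0.063, against 0.0024 to 0.063 over the alternatives). This list passed with the preset correlation (adjusted p = 0.029) and not with an estimated one (adjusted p = 0.32 with an estimated correlation). It was lost without parental control replicate 2 (0.051), with a normexp background (0.17), with the miRNAs detected on all 8 arrays (0.056) and with those of a mean signal of at least 50 (0.13), against adjusted p from 0.019 to 0.17 over the alternatives.

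Other families moved in part, and their lists did not pass. The miR-15/16 family, which represses BCL2, was lower in 4 of 4, by -1.03 for miR-15a, -0.51 for miR-16 and -0.51 for miR-15b, with camera at an adjusted p of 0.073, and of 0.035 with the replicate number as a block (adjusted p = 0.66 and 0.22 with an estimated correlation). Members of the let-7 family, which represses RAS, were higher in 5 of 9, led by let-7i at 2.06, while the abundant let-7a (-0.0027) and let-7f (0.05) were not called. The clusters of miR-17-92 and its paralogs, which MYC drives, went both ways, with 5 of 13 higher, such as miR-93 (1.03) and miR-106b (0.85), and 2 lower. Their median of 0.08 changed sign in 6 of the alternatives. In the growth-promoting list miR-221 (1.14) and miR-222 (0.99), which target CDKN1B, were higher and miR-21 (-0.43) lower, so that 2 of 3 were higher and 1 lower. Of the miR-30 family 4 of 6 were higher, among them miR-30b (0.56), and 1 lower, while miR-30e had 0.33 (adjusted p = 0.056). Adjusted over the list alone, 5 of the miR-30 family were higher, and the counts of the let-7, miR-15/16, miR-17-92 and growth-promoting lists were as over all tested. The miR-181 family had 2 of 4 lower both ways, miR-181c and miR-181d (-0.64), while miR-181a had -0.23, and the median of the family, -0.44, turned to 0.04 in 1 alternative. For the miR-29 family, which represses collagens, 0 of 3 were called either way, with 0.36 for miR-29b and 0.10 for miR-29a. Of the p53-induced miRNAs 2 of 5 were higher, miR-107 (0.73) and miR-192 (0.38), and 2 lower, miR-34a and miR-34c-5p, both over all tested and adjusted over the list alone. Single members stood for the Xq26-27 clusters, miR-424 at 1.19, and for hypoxia, miR-210, each called higher both ways. Of 9 tested viral miRNAs 1 was higher both ways, with values of -0.0019 for ebv-miR-BART12 and -0.24 for kshv-miR-K12-12. Their median was -0.0019 and the test pointed up. Of the calls named here, that of miR-192 was lost in 12 of 22 alternatives (adjusted p = 0.0094 to 0.13 over them), and over 23 alternatives calls were lost in 9 for miR-21 (0.0040 to 0.20), 5 for miR-15b (8.0e-04 to 0.15), 4 for miR-181d (0.0017 to 0.87), 3 for miR-30b (0.0025 to 0.089) and 2 for miR-16 (5.9e-04 to 0.072). This included the loss of parental control replicate 1 (adjusted p = 0.15 for miR-15b, 0.077 for miR-181d, 0.057 for miR-192, 0.20 for miR-21) or replicate 2 (0.079 for miR-192), of resistant control replicate 1 (0.076 for miR-15b, 0.068 for miR-181d, 0.066 for miR-192, 0.16 for miR-21, 0.056 for miR-30b) or replicate 2 (0.13 for miR-15b, 0.051 for miR-16, 0.057 for miR-181d, 0.10 for miR-192, 0.11 for miR-21), and of either resistant CDDP replicate (0.068 for miR-21).

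Under CDDP the lines differed in much the same miRNAs. The group means came from arrays other than those of the untreated groups. Both comparisons, however, took their spread, scaling and filter from all 8 arrays. miR-124 was at least 2237-fold lower in resistant cells and miR-124* at least 16.6-fold. miR-34b* (-3.64), miR-34a (-3.33), miR-9* (-3.21) and miR-181c (-2.18) were lower, as were miR-34a* (at least 11.4-fold), miR-363 (at least 8.46-fold), miR-34c-5p (at least 5.56-fold), miR-152 (at least 4.69-fold), miR-654-5p (at least 4.44-fold) and miR-95 (at least 4.28-fold). The bound for miR-152 was 2.83-fold without parental CDDP replicate 1 and 7.79-fold without replicate 2. Higher were miR-216a (at least 21.8-fold), miR-216b (at least 12.9-fold) and miR-217 (at least 7.59-fold), with miR-483-5p (3.45), miR-10a (3.03), miR-483-3p (2.95), miR-24-1* (2.82), miR-23b* (2.65), miR-210 (2.31), miR-23b (2.28), miR-27b (2.23) and miR-24 (1.99). Of the 24 miRNAs named by size in each comparison, 21 were shared.

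Limma called 159 of 340, 73 higher and 86 lower, with fitted changes of at least 2-fold in 22 and 56. The arrays did not overlap for 159 of the 159 called and for 69.4% of all, where chance gives 33.3%. Called higher in both line comparisons were 70 miRNAs, against 18.7 if the comparisons were independent, and called lower in both were 77, against 19.98. As the comparisons share their spread per miRNA and their slides, they are not independent, and these values are no measure of chance here. No miRNA was called with opposite signs, and the changes correlated across miRNAs with r = 0.979 and rho = 0.923. With a normexp background 72 were called, and 10 of the 30 named above and below for this comparison lost their call, miR-124*, miR-152, miR-181c, miR-217, miR-23b*, miR-34c-5p, miR-363, miR-485-5p, miR-654-5p and miR-95. With no scaling 21.8% of the calls were higher against 45.9%, as the median change of all miRNAs moved to -0.28 from 0.06.

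**Figure D3:**
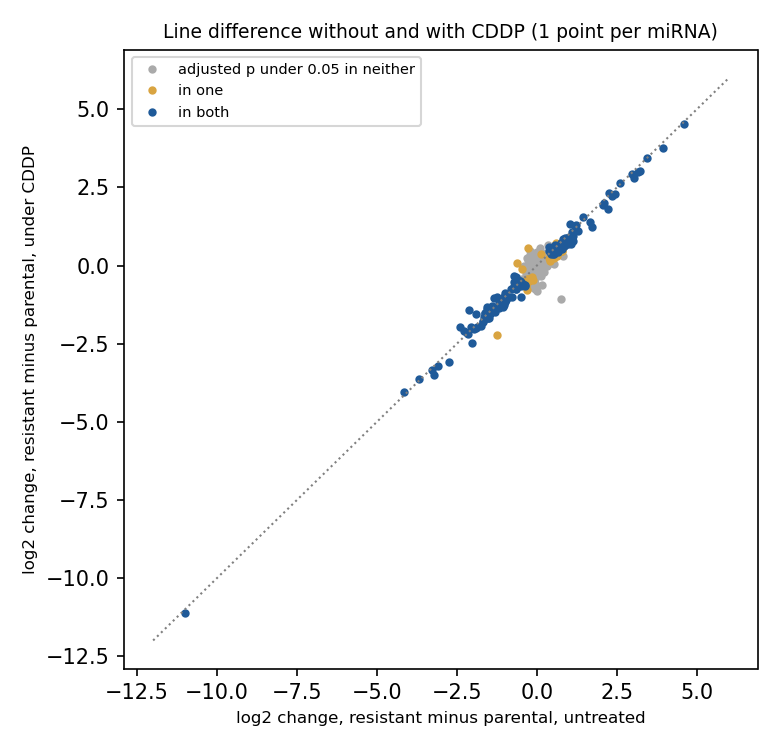
Log2 change between the lines (resistant minus parental) of each of the 340 tested miRNAs, untreated on the horizontal and under CDDP on the vertical axis. The dotted line marks equal changes, and miRNAs undetected in a group are drawn at their fitted values, which rest on the floor. The 70 miRNAs called higher and the 77 called lower in both comparisons (blue) lie along the line.

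The 14q32 cluster was lower under CDDP in 36 of 39, also when adjusted over the list alone, with a median of -1.27, by -2.01 for miR-381, -1.97 for miR-127-3p and -1.81 for miR-411, and at least 3.88-fold for miR-485-5p. Its list passed with the preset correlation (adjusted p = 6.5e-17) and not with an estimated one (adjusted p = 0.35 with an estimated correlation). The neuronal miRNAs were lower in 3 of 3 both ways, with -1.94 for miR-9 (preset adjusted p = 3.4e-03; adjusted p = 0.35 with an estimated correlation), a list call lost with no filter on dim miRNAs (0.073, against 3.4e-07 to 0.073 over the alternatives). The clusters of miR-23, miR-27 and miR-24 were higher in 3 of 5 both ways, with 0.13 for miR-23a (adjusted p = 0.40), a value that turned to -0.21 with no scaling. Their list passed with a preset adjusted p of 0.046 (adjusted p = 0.58 with an estimated correlation), and 12 of 20 alternatives kept the call. It was lost without each of parental CDDP replicate 2 (0.094), parental control replicate 1 and replicate 2 (0.062 each), resistant CDDP replicate 1 (0.051) and resistant control replicate 1 and replicate 2 (0.0504 each), and with both stricter filters on signal (0.078 and 0.074), against 6.4e-04 to 0.094 over the alternatives. The miRNAs that repress DNA repair genes were higher in 3 of 7, and in 4 of 7 when adjusted over the list alone, with camera at an adjusted p of 0.054. The miR-15/16 family was lower in 4 of 4 both ways, with an adjusted p of 0.054, and of 0.0495 with the replicate number as a block (adjusted p = 0.58 and 0.28 with an estimated correlation). The fragments of tRNA and rRNA were higher in 4 of 8 both ways, with a median of 0.62.

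Averaged over treatment, the resistant line kept the pattern of the single comparisons, whose 8 arrays it pools. Limma called 197 of 340, 103 higher and 94 lower, and all 24 miRNAs it named by size were named in 1 of the single comparisons or both. The share of calls that were higher, 52.3%, was 39.4% with no scaling, 38.1% with the deposited value table and 63.6% with a normexp background. Among the 24 miR-9* had -3.15, miR-34b* -3.67, miR-483-5p 3.45, miR-10a 3.13 and miR-210 2.29. The 14q32 cluster was lower in 38 of 39 both ways (preset adjusted p = 1.2e-17; adjusted p = 0.37 with an estimated correlation), and the neuronal miRNAs in 3 of 3 both ways (preset adjusted p = 6.4e-03; adjusted p = 0.37 with an estimated correlation), a call lost with no filter on dim miRNAs (0.083, against 6.1e-07 to 0.083 over the alternatives). For miR-493 of the 14q32 cluster, undetected in both resistant groups, a fitted fall is again not read as a change. The clusters of miR-23, miR-27 and miR-24 were higher in 4 of 5 both ways (preset adjusted p = 0.039; adjusted p = 0.63 with an estimated correlation), and the miRNAs that repress DNA repair genes in 5 of 7 both ways (preset adjusted p = 0.039; adjusted p = 0.37 with an estimated correlation). The former call held in 17 of 20 alternatives (0.0083 to 0.077) and the latter in 14 of 20 (0.022 to 0.12), and without parental control replicate 2 both lists had an adjusted p of 0.052. Among their members, the call of miR-23a held in 7 of 22 alternatives (0.024 to 0.94) and was lost without each array but parental CDDP replicate 1 (0.059 to 0.16), and that of miR-101 was lost with the deposited value table (0.072) and with no scaling (0.066), against 2.5e-04 to 0.072. The call of miR-100 held in 13 of 22 (0.0034 to 0.37) and was lost without parental control replicate 1 (0.067), resistant CDDP replicate 1 (0.062) and resistant control replicate 1 (0.061) or replicate 2 (0.062). The miR-15/16 family was lower in 4 of 4 both ways, with a camera adjusted p of 0.052, and of 0.029 with the replicate number as a block (adjusted p = 0.63 and 0.21 with an estimated correlation).

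In parental cells the comparison asked what a short exposure to CDDP did, and no single miRNA passed. The smallest p among higher values belonged to miR-34c-5p, with a log2 value of 0.45 ± 0.09 (SE, limma adjusted p = 0.69), its signal being 23.8 ± 0.898 (SD, n = 2) without and 32.7 ± 1.30 (SD, n = 2) with the drug. Next came miR-769-3p (0.36), miR-363 (0.35), miR-183* (2.33 ± 0.79) and miR-1207-5p (0.38). The value of miR-183* was 4.07 on slide 1 and 0.58 on slide 2, and 1.14 without parental CDDP replicate 1 and 3.51 without replicate 2. Among lower values the smallest p belonged to miR-485-3p (-0.45), miR-154* (-0.50), miR-493 (-0.38), miR-195* (-0.60) and miR-370 (-0.31). Limma called 0 of 340, with 15 at an unadjusted p under 0.05 where chance gives 17. The arrays did not overlap for 30.6% of miRNAs, where chance gives 33.3%. The median 95% interval reached 0.35 to either side, and for 300 of 340 it lay within 2-fold. The 340 include miRNAs undetected on every parental array, such as miR-216a. Their intervals rest on the floor and do not show what CDDP did. Without parental CDDP replicate 2, 1 miRNA was called, miR-152, singled out here after its values were seen (log2 value 1.71, adjusted p = 0.042).

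As groups, the 14q32 cluster had a median of -0.11 in CDDP-treated parental cells and the clusters of miR-17-92 and its paralogs a median of 0.20, with 0 of 39 and 0 of 13 members called, both over all tested and adjusted over the list alone. Among the latter were miR-20a (0.26), miR-93 (0.23) and miR-17 (0.22). Camera called the first lower (preset adjusted p = 6.0e-08; adjusted p = 0.74 with an estimated correlation) and the second higher (preset adjusted p = 7.0e-06; adjusted p = 0.74 with an estimated correlation), while fry passed neither (adjusted p = 0.45 and 0.34). By slide, the median of the 14q32 cluster was 0.02 and -0.26, and that of the miR-17-92 list 0.27 and 0.09. The 14q32 call was lost without parental CDDP replicate 2 (adjusted p = 0.17, against 1.6e-15 to 0.17 over the alternatives). A normexp background gave the cluster a median of 0.02 and ended the miR-17-92 call (0.13, against 5.7e-07 to 0.13). Of the 5 p53-induced miRNAs 0 were called over all tested and 1, miR-34c-5p, when adjusted over the list alone.

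In resistant cells the same exposure again gave no call for a single miRNA. Of the 5 higher values of smallest p, miR-769-3p (limma adjusted p = 0.19), miR-628-5p and miR-300 belonged to miRNAs undetected on all 4 resistant arrays, so none is read as a change. miR-193b had a log2 value of 0.39 ± 0.10 (SE) and miR-342-5p one of 0.35. The lower values of smallest p were miR-889 (-0.41), miR-7 (-0.45), miR-9 (-0.35), miR-1308 (-0.59) and miR-376b (-0.33). With a normexp background the values of miR-193b and miR-342-5p turned negative. Limma called 0 of 340, with 13 at an unadjusted p under 0.05 where chance gives 17, and 1 with a floor 4 times lower, miR-379*, which was undetected on all 4 resistant arrays and is named after its values were seen. The arrays did not overlap for 34.7% of miRNAs, where chance gives 33.3%, and the interval lay within 2-fold for 295 of 340. The 340 include miRNAs undetected on all 4 resistant arrays, such as miR-124 and miR-363. Their intervals rest on the floor and do not show what CDDP did. With no scaling the median of all miRNAs was -0.25 against -0.07.

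The 14q32 cluster had a median of -0.13 in CDDP-treated resistant cells, with -0.48 for miR-494, -0.32 for miR-376a and -0.31 for miR-154*, and 0 of 39 called both over all tested and adjusted over the list alone. Camera called the list lower (preset adjusted p = 2.3e-03; adjusted p = 0.98 with an estimated correlation), fry did not (adjusted p = 0.68), and by slide the median was -0.13 and -0.16. The call was lost with quantile normalization (0.18) and without resistant CDDP replicate 2 (0.26), against 4.5e-04 to 0.26 over the alternatives. The miR-17-92 list had a median of -0.02 while its test pointed up (camera adjusted p = 0.81), with 0 of 13 called both ways.

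Whether CDDP acted differently in the lines was tested as the difference of its effects, resistant minus parental. The miR-17-92 clusters had a median difference of -0.23, with -0.30 for miR-20b, -0.24 for miR-17* and -0.24 for miR-93, and 0 of 13 called both over all tested and adjusted over the list alone. Camera called the list lower (preset adjusted p = 8.5e-04; adjusted p = 0.90 with an estimated correlation), and fry did not (adjusted p = 0.37). The call was lost with quantile normalization (0.10), without resistant CDDP replicate 2 (0.14) and without resistant control replicate 1 (0.055), and with a normexp background the test pointed up (0.38), against 5.7e-04 to 0.38 over the alternatives. Single miRNAs of smallest p were miR-195* (0.84) and miR-370 (0.34) among higher values, and miR-7 (-0.49), miR-21* (-0.50) and miR-146b-5p (-0.36) among lower ones. miR-300, miR-628-5p, miR-493, miR-34c-5p and miR-363 were named by the same rule, but as none of these 5 was detected on a resistant array, none is read as a difference. Limma called 0 of 340 (each adjusted p = 1.00), with 6 at an unadjusted p under 0.05 where chance gives 17. For the 14q32 cluster the median was -0.04 while the test pointed up (camera adjusted p = 0.21).

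Averaged over lines, CDDP gave the smallest p to miR-769-3p (limma adjusted p = 0.14). It and miR-34c-5p were undetected on all 4 resistant arrays, miR-182* on both resistant control and miR-605 on both resistant CDDP arrays, so no value is given for these 4, which the rule named. The others were miR-193b with a log2 value of 0.32 ± 0.07 (SE) and miR-1207-5p (0.36) among higher values, and miR-485-3p (-0.30), miR-154* (-0.40), miR-889 (-0.29) and miR-9 (-0.26) among lower ones. The 14q32 cluster had a median of -0.12 (preset adjusted p = 8.1e-08; adjusted p = 0.75 with an estimated correlation) and the miR-17-92 clusters one of 0.09 (preset adjusted p = 3.1e-03; adjusted p = 0.84 with an estimated correlation), with 0 members of either called both over all tested and adjusted over the list alone. The latter call was lost without resistant CDDP replicate 1 (0.11) and without resistant control replicate 2 (0.12), against 1.2e-04 to 0.12 over the alternatives. Limma called 0 of 340, with 23 at an unadjusted p under 0.05 where chance gives 17. With the slide as a random block 1 was called, miR-769-3p (adjusted p = 0.045, against 0.045 to 1.00 over the alternatives), and 1 with a floor 4 times lower, miR-379* again.

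With the replicate number, which is also the slide, as a block in the fit, 189 miRNAs were called between the untreated lines, 177 between the lines under CDDP and 214 averaged over treatment, and 0 for CDDP in parental cells, in resistant cells, averaged over lines and for the difference of its effects.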

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

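Chosen only after the result was seen were the tests of array position, of the 3 explanations for the 14q32 cluster, of the CDDP split of the arrays and of the array column, while the split by line, the scaling and the noise of one slide were set beforehand.

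The miR-17-92 and paralogous clusters stood out because the effects of CDDP on them differed between the lines, with a median difference of -0.23, by camera with its preset correlation alone. The adjusted p was 8.5e-04 with that and 0.90 with an estimated correlation, and quantile normalization, a normexp background and the loss of resistant CDDP replicate 2 or resistant control replicate 1 each ended the call.

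Many miRNAs differed between the lines. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one by line, gave as many calls (204 in a fit with 2 groups), and the highest of the others gave 0. A random labelling of these arrays is thus argued against, at 1 in 35, the smallest share these splits can give. Every other split mixes the lines, which widens its spread, so the 0 does not measure noise within a line. Nor can the splits tell a difference between lines from one between cultures. Scaling as the whole cause is argued against by the lowest count over the other scalings, 137 against 166. For array position, which goes with line on both slides, 7 bright control features were compared. Their largest shift between the lines over all 8 arrays was 0.383 on the log2 scale. The median size among miRNAs called between the untreated lines was 1.00, and 2 of these had changes of at most 0.383. The controls were all higher in the resistant line, by 0.23 to 0.38 scaled and by 0.02 to 0.17 unscaled. A shift of the size seen in the controls falls short of most called changes. Controls need not show an effect of position on miRNA signals, however, so position cannot be excluded. A biological difference between the lines, untested here, may remain, and the labels do not say how or when they were separated.

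The 14q32 cluster was lower in the resistant line. A bias that goes with signal is argued against by random lists of matched signal, 0% of which had a median as low as -1.19. These were drawn from tested miRNAs outside the fixed list, which include unlisted ones of the locus. For cross-hybridisation among related sequences, the 22 members with no relative of the same number had a median of -1.24. Relatives were taken from the number in the name and not from the sequence, so this test cannot decide. The members' changes were also closer together than chance, with an SD as low in 0.43% of matched random lists, which may reflect 1 locus changing as a unit. This is a hypothesis found and tested on the same data, and neither the copy number nor the imprint of the locus was measured.

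Small values for CDDP were alike in both lines in part, with r = 0.380 across miRNAs between the mean effects, which share slides. With line and slide as terms, the split by CDDP called 1 miRNA, and 3 of the 33 splits of the arrays other than those by line and by slide gave as many, with 3 as the highest other count, so by calls chance cannot be excluded. Counts at an unadjusted p under 0.05 disagreed, with 44 for CDDP, as many in 1 of the 33 splits and 41 as the highest other, and, without slide as a term, 27, as many in 9 of 34 and 87 as the highest other, from the split by slide, which points to arrays of 1 slide being alike. Between slides, where the lines share no array, r was 0.105 and 0.232, against 0.142 (parental) and 0.231 (resistant) between slides within a line, and as only 1 of the 2 passed the 0.2 set for a shared effect and neither fell under the 0.1 set for noise of one slide, these cannot be told apart. Of the 4 CDDP arrays, 0 lay in the first array column, so an effect of the column cannot be told apart from one of CDDP either.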

How the results depend on the processing

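The filter at a mean scaled signal of 50 was chosen after the data were seen. Counts of called miRNAs over the alternatives lay between 112 and 189 for the untreated lines, 72 (normexp) and 177 under CDDP, and 132 and 214 averaged over treatment. miR-34a was called lower in the resistant line in all alternatives run for these comparisons, by -3.55 to -2.93 untreated. Counts for CDDP were 0 except for 1 in resistant cells and 1 averaged over lines with a floor 4 times lower, 1 averaged over lines with the slide as a random block, and 0 to 1 in parental cells when 1 array was left out. List calls over all comparisons numbered 26 with normexp and 11 with only the miRNAs detected on all 8 arrays, which leaves fewer to test, against 17. The value of miR-34a for the difference of the CDDP effects, never called, was 0.015 with the deposited gene signal, 0.18 with the brightest probe and 0.083 with quantile normalization, and -0.21 to 0.13 when 1 array was left out. For CDDP in resistant cells it was -0.040 with the deposited value table, -0.034 with no scaling, and -0.019 to 0.31 when 1 array was left out, a lone array being taken to vary like the other groups. Values of the following also changed sign, some from large changes such as -2.39 for miR-181c* untreated and 0.84 for the difference of miR-195*. Those of miR-300, miR-628-5p, miR-769-3p, miR-493 and miR-363 for CDDP in resistant cells or the difference are fits to undetected signals and not changes. With normexp, untreated, these were 0.10 (miR-181c*), 0.0084 (miR-363), 0.093 (miR-34c-5p), 0.24 (miR-485-5p), 0.22 (miR-628-5p), 0.11 (miR-654-5p) and 0.080 (miR-95), and averaged over treatment 0.093 (miR-485-5p). For CDDP in parental cells they were 0.13 (miR-195*) and 0.16 (miR-493), in resistant cells -0.11 (miR-193b), -0.12 (miR-300), -0.12 (miR-342-5p), -0.10 (miR-628-5p) and -0.12 (miR-769-3p), and for the difference -0.26 (miR-195*), -0.26 (miR-300), -0.050 (miR-370), -0.32 (miR-493) and -0.26 (miR-628-5p). Others were -0.22 and -0.21 (miR-23a under CDDP, value table and no scaling), and for the difference -0.18 (miR-300, brightest probe), 0.012 (miR-93, quantile) and 0.31 (miR-363, floor 4 times lower). The normexp alternative adds its offset of 50 to every spot before the sum over probes, which draws log2 changes of dim miRNAs toward 0. For these values and the counts above, except where fewer miRNAs were tested, no cause was tested, this one included. With no filter, 494 miRNAs at the floor on all arrays were kept out of the fit and counted as not called, since with them in it 664 were called untreated, 494 of them these. The random block, the trend and robust fit and the fit to the compared arrays were not run for lists. Signals near the floor limit what dim miRNAs can show.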

Other observations

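The test of neighbouring genes was chosen after the result was seen.

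Beyond the lists, 3 more miRNAs, singled out after their values were seen, were higher in untreated resistant cells. hsa-miR-10b, encoded among the HOXD genes, was higher by 1.45, and hsa-miR-132 and hsa-miR-212, neighbours in a CREB-regulated locus, by 0.94 and 1.12.

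Features named after viral miRNAs were detected on all 8 arrays for 7 of the 9 tested, with 606 ± 73.9 (SD, n = 8) for ebv-miR-BART12 and 284 ± 66.8 (SD, n = 8) for kshv-miR-K12-12. Only ebv-miR-BART13 was called among them between the untreated lines, with a change of 1.73.

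A further hypothesis was that miRNA genes of 1 cluster change together outside the 14q32 locus. Among 63 pairs of genes within 50 kb in GRCh38.p14, matched by name for 273 of 331 human tested miRNAs, the mean absolute difference of the changes was 0.54, and 0.8% of permutations of the changes over genes gave one as small, with a median of 0.89. With unlisted genes of the locus left in, 78 pairs gave 0.35%, and the wider exclusion was chosen after that. The result may reflect clusters changing together, as for miR-216a, miR-216b and miR-217. Pairs were set by distance alone, however, and need not belong to 1 cluster. Some neighbours went apart, such as miR-363 from miR-18b and miR-20b, and miR-181c from miR-23a, miR-27a and, in size, miR-181d. Related sequences within a cluster may also share signal.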
